A study of Homo sapiens with 18 samples.

How the data were processed

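LNCaP is an androgen-dependent human prostate cancer cell line. FOXA1 is a forkhead transcription factor that binds closed chromatin and opens it for other factors. Per the labels, the cells carried either the control vector pGIPZ or a short hairpin against FOXA1. Control cells and 1 line with the hairpin expressed GFP, and the other hairpin lines expressed wild-type FOXA1 or a mutant named G87R, D226N, M253K, F266S, L388M or FENG. The last name is not defined in the labels and is used here as given. Per the labels' protocols, cells were kept for 3 days in medium with 5% hormone-stripped serum and then given ethanol or 1 nM R1881, a synthetic androgen, for 24 hours. The 9 constructs under 2 treatments gave 18 arrays with 1 array per condition, and no source says that arrays came from separate cultures.

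Biotin-labelled total RNA was hybridised to Illumina HumanHT-12 V4 bead arrays, per the labels. The table deposited by the authors holds, per the file headers, a signal intensity and a detection p-value for each of 47303 probes on every array. GenomeStudio is named in the submitters' processing notes, with no version given. The lowest intensity was 68.4, so background had not been subtracted, and the arrays had not been brought to a common distribution. The deposited detection p-value moved in steps that correspond to about 775 negative controls per array. A second deposited table holds processed intensity values of the same arrays. Its values ran down to -15.4 with a median of 5.2 on every array, and within each array their ranks equalled those of the raw signal (rank correlation 1), so they had been background subtracted and given a common distribution on a linear scale. The steps used for that are not given in the sources used here. Slides and scan dates are not given in the sources used here, so no slide or date was tested as a batch. Columns belonging to other samples numbered 0.

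The raw intensity was analysed in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and matrixStats 1.5.0. The background was fitted from the detection p-values with limma's neqc method (offset 16), followed by quantile normalization and log2. A probe was kept if its detection p-value was under 0.01 on at least 2 arrays, which kept 20117 probes. The platform annotation gave 1 gene for 30102 probes, several genes for 8 and none for 17193, and 99.87% of the named probes had their symbol updated through the GRCh38.p14 gene table. Probes with several genes or none were left out of gene counts. For each gene the kept probe with the highest mean was used, which left 11590 genes. COXFA4L2 is the current symbol of NDUFA4L2. Among 59 named and called genes with more than 1 kept probe, 6 had another probe of opposite sign (AZIN1, PAOX, ACTB, TP53I3, PFKFB3 and TAGLN), and 14 had a probe over 1 log2 unit away. Probes of near-identical genes can take up each other's RNA, so values for the UGT2B, AKR1C, TRIM49/TRIM48/TRIM51, HLA-DR, KRT16, TUBA3 and SAA families are uncertain as to the family member.

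An additive limma fit over all 18 arrays, with construct and treatment as terms, gave 8 residual degrees of freedom. The residual is the difference between constructs in their response to R1881, and it stood in for the missing repeats of each condition. P-values therefore measure only this residual spread, which may be technical. From this fit came the androgen response, the FOXA1 knockdown (hairpin with GFP against control vector with GFP), re-expression of wild-type FOXA1 in hairpin cells, each of the 6 mutants against wild type, and a class contrast of D226N, M253K and F266S against G87R and L388M. The 3 residues of the first class lie in the forkhead, the DNA-binding domain of FOXA1, and those of the second lie outside it. The difference in response between D226N, M253K and F266S and the set of wild type, G87R and L388M was fitted on the R1881 minus ethanol differences, with 4 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was the threshold in all 11 comparisons. Changes are log2 differences with their standard error. Where a gene was undetected on all arrays of a group, its fold is a bound ("at least"). The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own value and the lowest value among detected probes.

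A total of 21 gene lists (521 entries) were written before the data were examined. They cover androgen-induced and androgen-repressed genes, FOXA family and cofactor genes, luminal epithelial, basal epithelial, neuroendocrine and neuronal, mesenchymal, and leukocyte, endothelial and fibroblast markers, S phase, G2/M, inflammatory cytokines, interferon response, hypoxia and glycolysis, unfolded protein response, ATF4 and amino acid stress, cholesterol and fatty acid synthesis, polyamine metabolism, p53 targets, TGF-beta response, WNT response and housekeeping genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and limma's fry as alternatives. For values from 1 array per condition no test was made, and a list's median was placed among 10000 random lists of the same size matched on mean expression. The androgen-induced list was compared between 3 and 3 constructs with an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1.

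Named genes followed a rule fixed before the data were examined. FOXA1, KLK3, TMPRSS2 and FKBP5 were taken in each comparison. The 10 largest called changes in each direction (5 for each mutant and for the difference in response) with the same direction in all 9 constructs or under both treatments were added, together with up to 4 called members of each list. Where no gene passed, the 3 largest values in each direction were taken. The text names part of these.

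The fits were tested on simulated data for the 11590 genes with 67 of them changed by 0.5 log2 units, 67 by 1 and 66 by 2. For the androgen response, 70.15% of genes changed by 0.5 log2 units were recovered and 98.51% of those changed by 1. For the knockdown these shares were 2.985% and 67.16%, for the class contrast 49.25% and 94.03%, and for the difference in response 0% and 40.3%. False calls made up 4.301%, 4.348%, 8.475% and 3.333% of the calls. The simulated noise was independent for each gene and array, with no deviation shared by genes and no spread between constructs of a class. These shares may therefore be better than in the real data. Alternatives covered the background correction, the normalization, the authors' processed values (negative values set to 0, offset 16), the filter on dim probes, the mean over a gene's probes, an intensity trend, array weights, a fold of at least 1.5, other models and arrays left out in turn.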

Results

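Gene expression was measured in LNCaP prostate cancer cells in which FOXA1 had been knocked down and replaced by wild-type or mutant FOXA1, with and without androgen. The series asked how FOXA1 mutants alter gene expression and its response to androgen. Each of 9 constructs was arrayed once with ethanol and once with 1 nM R1881, so each construct had 2 arrays and each treatment 9. A comparison of a pair of constructs sets 2 arrays against 2, the class contrast sets 6 against 4, and every called gene named below in these had the same direction under both treatments. Mean raw signal per array ran from 233.1 to 303.9 (median 265.3), and 15855 to 17278 probes were detected (median 16788). By a score for each array, M253K ethanol, FENG R1881 and G87R ethanol shared a deviation (-2.25, -0.99 and -0.68, other arrays at 0.52 or above). They are called the deviating arrays below, although the additive fit alone cannot tell which array of a construct deviates. Fits without them were added after the data had been examined. The number of arrays limits the precision: the median standard error was 0.0868 log2 units for the androgen response, 0.1841 for a comparison of a pair of constructs and 0.1188 for the class contrast.

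The probe for FOXA1 was brightest in control cells on both treatments. Its log2 intensity in ethanol was 11.92 in control cells, 11.15 in knockdown cells, 10.85 with wild-type FOXA1, 10.88 with G87R, 10.75 with D226N, 11.09 with M253K, 10.95 with FENG, 11.04 with F266S and 10.95 with L388M. With R1881 it was 11.72, 11.07, 10.67, 10.60, 10.73, 10.82, 10.93, 11.01 and 10.71 in the same order. The knockdown difference was -0.71 ± 0.12 (SE), a 1.64-fold lower signal (limma adjusted p = 0.00287). With wild-type FOXA1 put back, the signal was not higher than in knockdown cells (-0.35 ± 0.12, adjusted p = 0.162), and no mutant differed from wild type (adjusted p from 0.295 to 1.00 over the 6 mutants). Which part of the transcript this probe reads, and whether it reads the inserted copies, is unknown. It thus checks the hairpin in GFP cells only. In cells with inserted FOXA1 its signal cannot tell the effect of the hairpin from the level of the insert. FOXA1 was lower with R1881 in 9 of 9 constructs, by a change that did not pass (-0.15 ± 0.06, adjusted p = 0.130).

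R1881 raised the textbook androgen targets of prostate cells in every construct. FKBP5, an HSP90 co-chaperone, rose from a mean log2 intensity of 8.16 to 11.05, a 7.42-fold increase (2.89 ± 0.10, adjusted p = 1.24e-08). KLK3, which encodes prostate-specific antigen, rose by 1.52 ± 0.10 (adjusted p = 1.04e-06) and TMPRSS2, a surface serine protease, by 1.48 ± 0.13 (adjusted p = 8.41e-06). Among the 10 largest increases were the transcription factors SNAI2 (2.92 ± 0.16) and MAF (2.67 ± 0.15), the kinase SGK1 (2.34 ± 0.20), the kallikrein KLK2 (1.97 ± 0.15), PMEPA1 (1.90 ± 0.12) and the glucose transporter SLC2A3 (at least 2.48-fold). The largest decreases were of LRRN1 (-1.96 ± 0.12) and OPRK1, the kappa opioid receptor (-1.74 ± 0.10), followed by PCED1B (-1.60), HOXA11-AS (-1.56), MID1 (-1.56), PLD1 (-1.55) and IL1RN (-1.54). In total 681 genes rose and 879 fell, of which 925 had the same direction in all 9 constructs, and 210 and 184 changed by at least 1.5-fold. With median scaling in place of quantile normalization 941 genes passed.

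Of 46 measured androgen-induced genes, 41 rose and 0 fell (43 rose when adjusted over the list alone; camera adjusted p = 8.17e-49, and adjusted p = 0.0149 with an estimated correlation). The androgen-repressed list was mixed, with 14 members lower and 6 higher of 27 (16 and 7 adjusted over the list alone). OPRK1, SLC44A1 (-0.99) and DDC (-0.99) fell, and HES6 rose by 1.38. Cholesterol and fatty acid synthesis moved upward, with 14 of 26 genes higher and 0 lower (16 adjusted over the list alone), among them the desaturases FADS1 (0.78) and FADS2 (0.75), the elongase ELOVL5 (0.75) and fatty acid synthase FASN (0.68). Its camera adjusted p was 3.21e-09, but the adjusted p was 0.072 with an estimated correlation. Hypoxia and glycolysis genes rose in 10 cases and fell in 1 of 24 (12 and 1 adjusted over the list alone; adjusted p = 0.079 with an estimated correlation), led by SLC2A3 and NDRG1 (1.76). Endoplasmic reticulum and unfolded protein genes rose in 4 of 20 (8 adjusted over the list alone; camera adjusted p = 1.65e-05, adjusted p = 0.230 with an estimated correlation), with CREB3L4 at 0.94. Polyamine enzymes included ODC1, the rate-limiting decarboxylase, at 1.53 ± 0.07, with 3 of 12 members higher and 1 lower (camera adjusted p = 0.0354, adjusted p = 0.339 with an estimated correlation).

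WNT response genes fell in 5 of 11, including LEF1 (-0.75), TLE1 (-0.41), TLE3 (-0.33) and RNF43 (at least 1.48-fold lower; camera adjusted p = 0.00845, adjusted p = 0.339 with an estimated correlation). G2/M genes fell in 3 of 29 (DLGAP5 by -0.29, PTTG1 by -0.28, AURKA by -0.23; camera adjusted p = 0.0065, adjusted p = 0.340 with an estimated correlation). Among p53 targets 4 of 17 fell, led by TP53INP1 (-1.06) and SESN1 (-0.65), without a camera call (adjusted p = 0.075). Luminal genes split, with SPDEF (1.52), GRHL2 (0.93) and KRT8 (0.76) among 4 that rose and GATA2 (-0.57) among 3 that fell of 19. SPDEF, GRHL2 and GATA2 also belong to the FOXA family and cofactor list, where 2 of 12 rose and 2 fell. Counts of higher and lower members were 3 and 5 of 18 for inflammatory cytokines, 3 and 2 of 23 for interferon response, 4 and 1 of 15 for TGF-beta response, 2 and 1 of 9 for mesenchymal, 2 and 1 of 7 for neuroendocrine, 2 and 0 of 26 for S phase, 1 and 2 of 26 for ATF4 and 1 and 1 of 6 for leukocyte, endothelial and fibroblast markers. None of 15 housekeeping and 5 basal genes passed in limma's test.

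**Figure D1:**
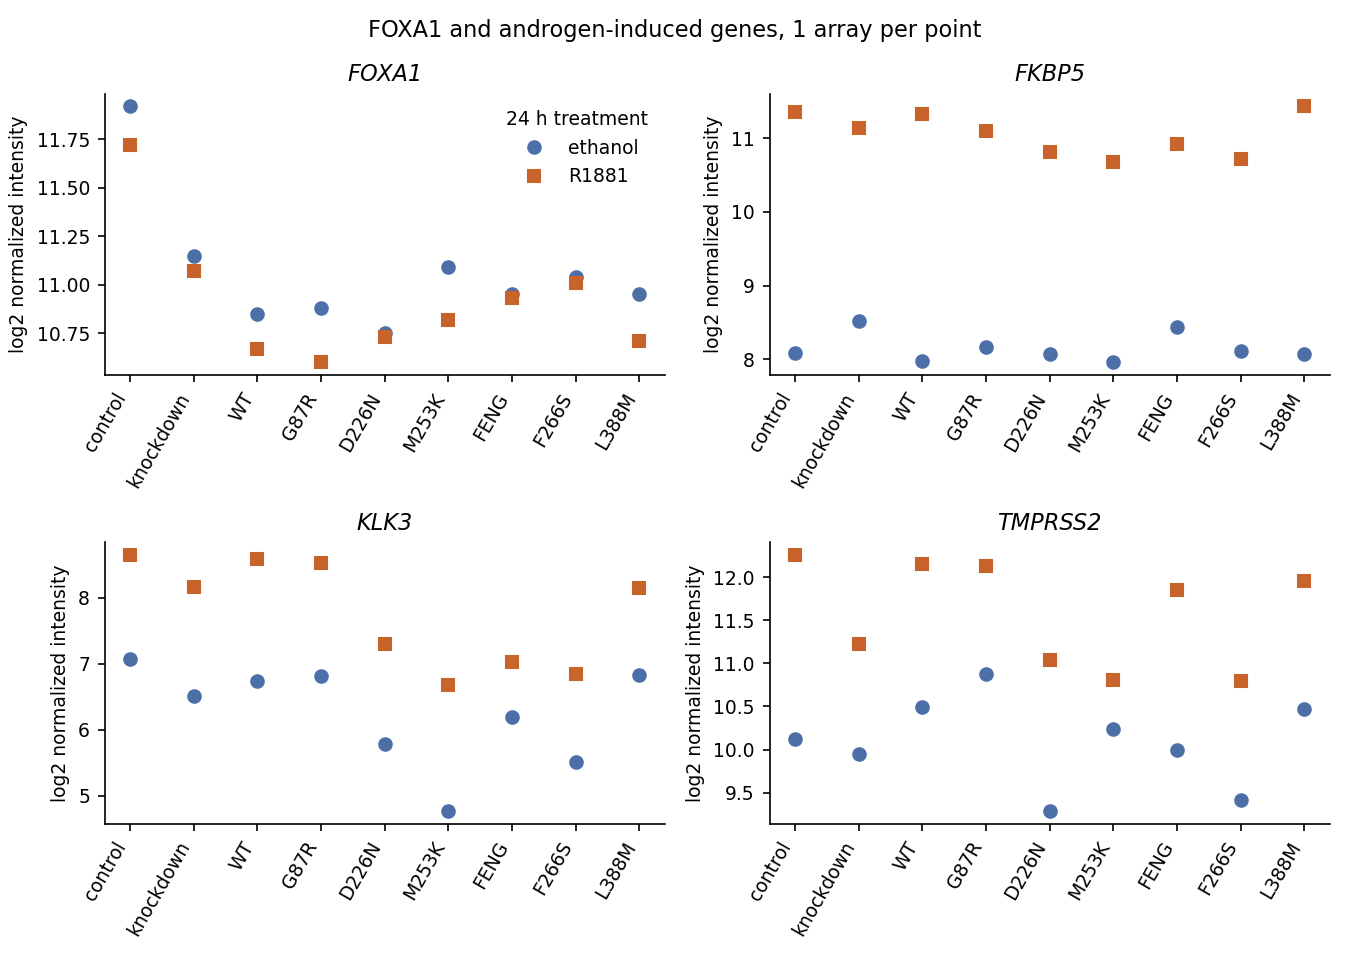
Log2 normalized intensity (vertical axis, range differing between panels) of FOXA1, FKBP5, KLK3 and TMPRSS2 in each of 9 constructs (horizontal axis), with circles for ethanol and squares for R1881, 1 array per point. FOXA1 is highest in control cells (11.92 and 11.72), and FKBP5 lies at 8.515 or below in ethanol and at 10.68 or above with R1881.

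Knockdown of FOXA1 raised PI3, MGP and HLA-DRA and lowered OR51E1, TFF3 and SLC45A3. PI3, an elastase inhibitor, was 81.5-fold higher in knockdown than in control cells (6.35 ± 0.13, adjusted p = 1.04e-11), and MGP, a matrix protein undetected in control cells, was at least 81.8-fold higher (adjusted p = 2.19e-07). The MHC class II gene HLA-DRA (5.61 ± 0.20), the calprotectin subunits S100A9 (5.04 ± 0.24) and S100A8 (at least 17.9-fold), RGS4 (at least 26.4-fold), PIP (at least 22.4-fold), S1PR3 (4.62), the protease MMP7 (4.11 ± 0.17) and SLPI (at least 14.0-fold) were also among the 10 largest increases. Lower in knockdown cells were the prostate olfactory receptor OR51E1 (-2.64 ± 0.17), TFF3 (-2.46), COXFA4L2 (-2.41 ± 0.32), the relaxins RLN1 (-2.38) and RLN2 (-1.95), DDC (-2.37 ± 0.19), SLC45A3 or prostein (-2.11 ± 0.22), TMEFF2 (-1.92) and WNT5A (at least 2.73-fold). KLK3 (-0.53 ± 0.21, adjusted p = 0.171), TMPRSS2 (-0.61, adjusted p = 0.225) and FKBP5 (0.10, adjusted p = 0.878) did not pass.

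In all, 528 genes were higher and 434 lower after knockdown. Inflammatory cytokine genes were higher in 12 of 18 and lower in 0 (14 adjusted over the list alone; camera adjusted p = 2.30e-19, and adjusted p = 0.00108 with an estimated correlation), among them SAA1 (at least 9.47-fold), CCL2 (3.65 ± 0.16), LCN2 (3.32 ± 0.21) and CXCL8 (3.09 ± 0.13). In G2/M 11 of 29 genes were lower and 0 higher (20 adjusted over the list alone; adjusted p = 0.083 with an estimated correlation), with the mitotic kinase AURKB at -1.25 and NUSAP1 at -1.03, and in S phase 9 of 26 were lower (19 adjusted over the list alone; adjusted p = 0.083 with an estimated correlation), with GMNN at -1.03 and UHRF1 at -0.93. Hypoxia genes were lower in 6 of 24 (8 adjusted over the list alone; camera adjusted p = 2.59e-06, adjusted p = 0.083 with an estimated correlation), including ANKRD37 (-1.53), ADM (-1.02) and the glycolytic regulators PFKFB3 and PFKFB4. Mesenchymal genes were higher in 4 of 9 (ACTA2 by 3.18, SNAI2 by 1.39, FN1 at least 1.85-fold; adjusted p = 0.083 with an estimated correlation) and basal genes in 3 of 5 (LAMB3 at least 5.57-fold; adjusted p = 0.286 with an estimated correlation). TGF-beta genes were higher in 4 of 15 (THBS1 by 2.66; adjusted p = 0.119 with an estimated correlation) and interferon genes in 3 of 23 (CXCL10 by 1.19; adjusted p = 0.083 with an estimated correlation). Among androgen-repressed genes 9 of 27 were lower and 4 higher (13 and 6 adjusted over the list alone; camera adjusted p = 0.0218, adjusted p = 0.165 with an estimated correlation). Of 19 luminal genes 2 were higher and 1 lower, without a camera call (adjusted p = 0.858). The androgen-induced list went both ways, with TRPM8 (3.33) and SGK1 (2.91) among 5 higher and SLC45A3 and LRIG1 (-1.46) among 4 lower of 46 (camera adjusted p = 0.368). The count fell to 563, 492, 475 and 461 without the control ethanol, knockdown ethanol, control R1881 and knockdown R1881 array, and to 533 with median scaling.

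Putting wild-type FOXA1 back lowered several of the genes that the knockdown had raised. HLA-DRA (-4.25 ± 0.20), S100A8 (-4.01), PI3 (-3.73 ± 0.13), CCL8 (-3.45), SERPINB7 (-3.36), S100A9 (-3.12) and CD74 (-3.11) were lower than in knockdown cells, and KRT16 was at least 6.19-fold lower. Higher were S100P (2.84 ± 0.19), the androgen-conjugating enzymes UGT2B28 (2.68 ± 0.24) and UGT2B11 (2.60), TNFRSF19 (2.65), the HES family regulator HES6 (2.51 ± 0.19) and the TRIM family genes TRIM49D1 (3.40 ± 0.59), TRIM48 (2.96) and TRIM51 (2.64). S100P and these TRIM genes had not passed in the knockdown (adjusted p = 0.545, 0.215, 0.272 and 0.358). That comparison averages both treatments. With R1881, knockdown cells lay below control cells for TRIM48 (6.055 against 8.452), TRIM51 (8.046 against 10.21) and TRIM49D1 (6.096 against 8.473). In ethanol the values were 4.893 against 4.918, 7.353 against 7.096 and 4.893 against 5.199, all from single arrays without a test. For the re-expression the totals were 235 higher and 301 lower, and KLK3 (0.33, adjusted p = 0.525), TMPRSS2 (0.74, adjusted p = 0.185) and FKBP5 (-0.17) did not pass. Inflammatory genes were lower in 10 of 18 and higher in 0 (12 adjusted over the list alone; camera adjusted p = 1.40e-16, adjusted p = 0.0019 with an estimated correlation), with CCL2 at -2.97 and CXCL8 at -2.19. Hypoxia genes were higher in 3 of 24 (7 adjusted over the list alone; ADM by 1.11; adjusted p = 0.202 with an estimated correlation). Camera called 8 lists in this comparison, not all of which are given here. The TGF-beta genes TGFB3 (at least 3.31-fold), ID1 (at least 1.84-fold), THBS1 (-1.20) and ID2 (-0.81) and the basal gene LAMB3 (-2.26) were lower. The G2/M list had 1 higher gene of 29, AURKB (0.73; adjusted p = 0.251 with an estimated correlation), and in the S phase list, called by camera, 0 of 26 genes passed limma's adjusted test (adjusted p = 0.278 with an estimated correlation). Androgen-repressed genes were higher in 8 of 27 and lower in 4 (9 and 6 adjusted over the list alone, list adjusted p = 0.202 with an estimated correlation). UGT2B28, UGT2B11, HES6 and BCHE were among the higher ones. Androgen-induced genes were higher in 2 and lower in 2 of 46, with SLC45A3 at 2.17 and SGK1 at -2.02 (adjusted p = 0.640 with an estimated correlation).

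Of the genes called in both the knockdown and the re-expression, 420 of 422 had opposite directions, 266 of them higher after knockdown (13.71 for independent lists) and 154 lower (8.8 for independent lists). Both comparisons use the knockdown arrays, which by themselves give opposite changes. Across genes, which are not independent replicates, r was -0.83 against -0.50 in 100 simulations without effects, and the covariance was -0.1475 against -0.027, a difference of -0.120. Part of the excess of counts over independent lists may come from the shared arrays, whose effect on r and the covariance the simulations already hold. Without the knockdown ethanol, wild-type ethanol, knockdown R1881 and wild-type R1881 array the re-expression count was 257, 211, 276 and 207, and with median scaling 326, with 175 higher and 151 lower.

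G87R and L388M, the mutants with residues outside the forkhead, had few genes called against wild type. For G87R 0 genes passed in limma (192 at an unadjusted p under 0.05), and no list was called. The largest values that did not pass were STPG1 (at least 1.18-fold higher) and ATG4B (-1.08 ± 1.00). ATG4B was at -1.99 in ethanol, on the deviating G87R array, and -0.17 with R1881. CCL2 was at -0.41 ± 0.16 and KLK3 at 0.0078 ± 0.21. For L388M 1 gene passed in limma (248 unadjusted): PI3, 2.36-fold above wild type (1.24 ± 0.13, adjusted p = 0.00446). Its inflammatory list was called by camera (adjusted p = 1.05e-09, and adjusted p = 0.0120 with an estimated correlation), although no member passed over all genes and 7 of 18 were higher when adjusted over the list alone, with SAA1 at 0.88 and TNFAIP3 at 0.85. Its hypoxia list was called with 0 genes (adjusted p = 0.440 with an estimated correlation), and KLK3 was at -0.17 ± 0.21. The PI3 call was lost with median scaling (0.97, adjusted p = 0.774) and without each of the 4 arrays of wild type and L388M in turn (0 genes each). With an array left out PI3 stayed 2.22-fold to 2.50-fold higher with a standard error of 0.17 in place of 0.13 (adjusted p from 0.0591 to 0.227).

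Against wild type, AKR1C2, UGT2B28 and CXCL8 were higher and KLK3 was lower with D226N. Knockdown cells with GFP also lay above wild type for AKR1C2 (9.795 against 7.239 in ethanol), but below it for UGT2B28 (4.771 against 7.782). A value above wild type can thus mean that a mutant did not reverse the knockdown. AKR1C2, a hydroxysteroid dehydrogenase, was higher than in wild type by 3.24 ± 0.17, UGT2B28 by 2.95 ± 0.24, AKR1C4 by 2.86, UGT2B11 by 2.79 and UGT2B10 by 2.62. COXFA4L2 (-2.19 ± 0.32), NAALAD2 (-1.84), the imprinted gene PEG3 (-1.75), OR51E1 (-1.56) and ACP3, prostatic acid phosphatase (-1.46 ± 0.14), were lower, as was KLK3 (-1.12 ± 0.21, adjusted p = 0.0190). TMPRSS2 was at -1.16 (adjusted p = 0.0667) and FKBP5 at -0.21. Inflammatory genes were higher in 7 of 18 (11 adjusted over the list alone; camera adjusted p = 1.42e-19, adjusted p = 0.00104 with an estimated correlation), with CXCL8 at 1.98 and TNF at 1.65. ATF4 targets were higher in 3 of 26 (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.104 with an estimated correlation), namely the cystine transporter SLC7A11 (1.04), CEBPB (0.80) and asparagine synthetase ASNS (0.52), and hypoxia genes were lower in 3 of 24 (6 adjusted over the list alone; PFKFB4 by -1.07; adjusted p = 0.102 with an estimated correlation). Androgen-repressed genes were higher in 5 of 27 and androgen-induced genes lower in 2 of 46 (adjusted p = 0.143 and 0.560 with an estimated correlation). Those 5 include UGT2B28, UGT2B11, UGT2B10 and UGT2B17, of uncertain family member. With R1881, UGT2B28 was higher in every construct and UGT2B11 in all but knockdown, while UGT2B10 and UGT2B17 were lower in most. The G2/M list was called as higher (mean 0.12) with 0 of 29 genes (adjusted p = 0.560 with an estimated correlation). In all 163 genes passed, and the share higher, 71.2%, was 58.5% without background correction and 84.3% with median scaling, where 89 genes passed, and 60.8% without the 3 deviating arrays, where 347 passed. Without the wild-type ethanol, D226N ethanol, wild-type R1881 and D226N R1881 array the count was 54, 44, 41 and 50.

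Set against wild type, M253K had 985 higher and 536 lower genes. PI3 was higher by 4.24 ± 0.13, the serpin SERPINB7 by 4.03, AKR1C2 by 4.02, the chemokine CCL8 by 3.93 and the protease MMP10 by 3.93. TRIM49D1 (-3.97), TRIM51 (-3.24), GRM5P1 (-3.14) and TRIM48 (-2.91) were lower. KLK3 was 3.84-fold lower (-1.94 ± 0.21, adjusted p = 6.52e-05), whereas TMPRSS2 (-0.80, adjusted p = 0.0762) and FKBP5 (-0.34) did not pass. Inflammatory genes were higher in 14 of 18 (15 adjusted over the list alone; adjusted p = 0.00188 with an estimated correlation), with LCN2 at 3.84 and SAA1 at 3.80. ATF4 targets were higher in 11 of 26 (18 adjusted over the list alone; CEBPB 1.63, ATF5 1.53; adjusted p = 0.073 with an estimated correlation). Cell cycle genes were lower, 16 of 29 in G2/M (21 adjusted over the list alone; CDK1 -1.46, NDC80 -1.24; adjusted p = 0.073 with an estimated correlation) and 9 of 26 in S phase (15 adjusted over the list alone; RRM2 -1.54, CDC45 -1.17; adjusted p = 0.119 with an estimated correlation). Hypoxia genes were lower in 5 and higher in 2 of 24, with PFKFB4 at -1.27 and ADM at 1.28. Interferon genes were higher in 6 of 23 (IFI27 1.55), TGF-beta genes in 5 of 15 (TGFB3 at least 3.10-fold), basal genes in 3 of 5 (LAMB3 3.19) and the leukocyte, endothelial and fibroblast markers in 1 of 6 (COL3A1, a fibroblast collagen, 0.83). With an estimated correlation their adjusted p was 0.073, 0.194, 0.194 and 0.187, and that of the hypoxia list 0.194. The M253K ethanol array stood apart, with a score of -2.25, the fewest detected probes (15855) and basal and leukocyte, endothelial and fibroblast list means (6.21 and 5.67) above the other ethanol arrays, and without the 3 deviating arrays 790 genes were higher and 778 lower. The share higher, 64.8%, was 44.4% with median scaling (956 genes), the count was 535 with array weights, and it was 620, 626 and 3204 without the wild-type ethanol, wild-type R1881 and M253K R1881 array.

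Several of the genes higher with D226N and M253K than with wild type were also higher with F266S. SERPINB7 (3.72 ± 0.16), AKR1C2 (3.63), PI3 (3.37), AKR1C4 (3.19) and the carboxypeptidase inhibitor LXN (3.03) were higher than with wild type. COXFA4L2 was lower by the largest amount (-3.90 ± 0.32), followed by OR51E1 (at least 4.48-fold), TFF1 (at least 3.98-fold), NAALAD2 (-2.29) and PEG3 (-2.04). Both KLK3 (-1.49 ± 0.21, adjusted p = 0.00109) and TMPRSS2 (-1.22 ± 0.27, adjusted p = 0.0198) were lower, and FKBP5 was at -0.24. Inflammatory genes were higher in 9 of 18 (12 adjusted over the list alone; CXCL8 2.79, CCL20 2.16; adjusted p = 0.00244 with an estimated correlation) and ATF4 targets in 6 of 26 (10 higher and 1 lower adjusted over the list alone; SLC7A11 1.86, ATF5 1.59; adjusted p = 0.097 with an estimated correlation). Hypoxia genes were lower in 7 and higher in 1 of 24 (13 and 1 adjusted over the list alone), with PFKFB4 at -1.69, PFKFB3 at -1.55, PFKP at -1.18 and P4HA1 at -1.13 (adjusted p = 0.087 with an estimated correlation). Androgen-repressed genes were higher in 7 and lower in 3 of 27 (adjusted p = 0.180 with an estimated correlation). The higher ones include UGT2B28, UGT2B11 and UGT2B10, of uncertain family member. In the S phase list 1 gene of 26, GMNN, was lower (-0.65, list adjusted p = 0.444 with an estimated correlation). The totals were 410 higher and 237 lower. They came to 335 with median scaling and to 211, 277, 207 and 205 without the wild-type ethanol, F266S ethanol, wild-type R1881 and F266S R1881 array.

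With FENG, which the labels do not define, SERPINB7 (3.63 ± 0.16), LXN (3.55), MMP10 (3.44), HLA-DRA (3.37), AKR1C2 (3.32), UGT2B28 (2.87) and UGT2B11 (2.82) were higher than with wild type. Lower than with wild type were TRIM49D1 (-3.79 ± 0.59), COXFA4L2 (-3.05 ± 0.32), GRM5P1 (-2.77), TRIM51 (-2.76) and KLK3 (-1.05 ± 0.21, adjusted p = 0.0116), while TMPRSS2 (-0.40, adjusted p = 0.487) and FKBP5 (0.03) did not pass. Inflammatory genes were higher in 11 of 18 (14 adjusted over the list alone; SAA1 3.04, CXCL8 2.95; adjusted p = 0.00103 with an estimated correlation) and ATF4 targets in 8 of 26 (10 adjusted over the list alone; SLC7A11 1.52, SLC3A2 1.23; adjusted p = 0.0998 with an estimated correlation). Hypoxia genes were lower in 3 of 24, S phase genes in 1 of 26 (POLE2 -0.66) and G2/M genes in 0 of 29, and TGF-beta genes were higher in 3 of 15, interferon genes in 3 of 23 and basal genes in 1 of 5 (LAMB3 2.57). Their adjusted p with an estimated correlation was 0.243, 0.284, 0.292, 0.284, 0.111 and 0.292. In all 432 genes were higher and 255 lower, and without the 3 deviating arrays, FENG R1881 among them, 373 and 242. With median scaling 328 passed, and without the wild-type ethanol, wild-type R1881 and FENG R1881 array 197, 206 and 299.

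**Figure D2:**
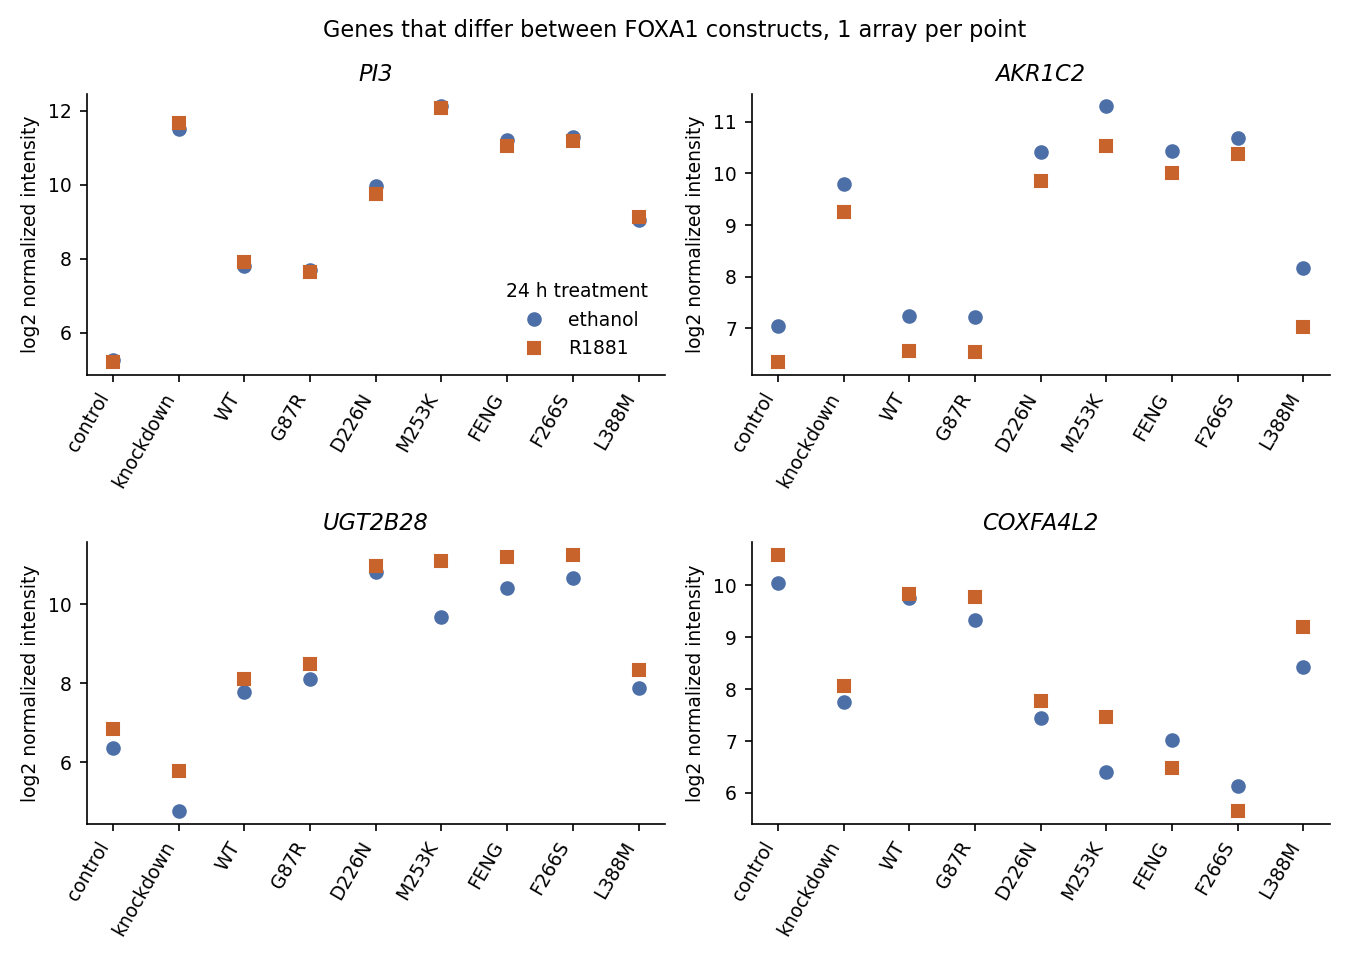
Log2 normalized intensity (vertical axis, range differing between panels) of PI3, AKR1C2, UGT2B28 and COXFA4L2 in each of 9 constructs (horizontal axis), with circles for ethanol and squares for R1881, 1 array per point. In the D226N, M253K, FENG and F266S arrays PI3 lies at 9.743 or above and COXFA4L2 at 7.777 or below, and in the wild-type and G87R arrays PI3 lies at 7.916 or below and COXFA4L2 at 9.337 or above. L388M lies between, with PI3 at 9.06 and 9.13 and COXFA4L2 at 8.421 and 9.2.

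Set against G87R and L388M, the forkhead mutants D226N, M253K and F266S had 833 higher and 639 lower genes. The p-values of this contrast rest on the residual of the additive fit and do not measure the spread between constructs of a class. Another grouping, D226N, G87R and L388M against M253K and F266S, called 1554 genes against 1472, so the calls do not set the forkhead class apart from other groupings. AKR1C2 was 9.83-fold higher (3.30 ± 0.11, adjusted p = 1.70e-09), with SERPINB7 at 2.98 ± 0.10, MMP10 at 2.97 ± 0.12, AKR1C4 at 2.75 ± 0.38, PI3 at 2.68 ± 0.08, LXN at 2.66, HLA-DRA at 2.57, UGT2B28 at 2.55 and endothelin EDN1, undetected in G87R and L388M, at least 5.13-fold. COXFA4L2 (-2.37 ± 0.20), NAALAD2 (-2.18 ± 0.16), PEG3 (-2.09), the trefoil peptide TFF1 (-1.79), the death-associated kinase DAPK1 (-1.58) and OR51E1 (-1.54) were lower. KLK3 was 2.70-fold lower (-1.44 ± 0.14, adjusted p = 1.71e-05) and TMPRSS2 2.14-fold lower (-1.10 ± 0.18, adjusted p = 0.00127), while FKBP5 was at -0.29 ± 0.14 (adjusted p = 0.216) and FOXA1 at 0.12 ± 0.08 (adjusted p = 0.384).

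Inflammatory genes were higher in 13 of 18 cases and lower in 0 (15 adjusted over the list alone; camera adjusted p = 5.58e-18, adjusted p = 0.00142 with an estimated correlation), among them CXCL8 (2.48 ± 0.08), LCN2 (2.32), CCL2 (2.26) and TNF (2.03). ATF4 targets were higher in 12 of 26 (14 adjusted over the list alone; SLC7A11 1.63, CEBPB 1.07, ATF5 1.03; adjusted p = 0.061 with an estimated correlation). Hypoxia and glycolysis genes were lower in 12 and higher in 1 of 24 (16 and 2 adjusted over the list alone; adjusted p = 0.084 with an estimated correlation). PFKFB4 was at -1.16 and PFKP at -0.89, and the 1 higher gene was the vasodilator peptide ADM (0.90). Cell cycle genes were lower in 8 of 29 for G2/M (15 adjusted over the list alone; TOP2A -0.50) and 6 of 26 for S phase (10 adjusted over the list alone; UHRF1 -0.51), with an adjusted p of 0.226 and 0.252 with an estimated correlation. Against wild type the mean over the G2/M list was 0.12 in D226N, -0.60 in M253K and -0.09 in F266S. Without M253K, whose ethanol array deviates, the class contrast had 0 lower genes in limma in each of these lists (means of -0.06 and -0.12, against -0.27 and -0.26). Among androgen-induced genes 11 were lower and 4 higher of 46 (15 and 5 adjusted over the list alone; adjusted p = 0.489 with an estimated correlation), with the prostaglandin dehydrogenase HPGD (1.80) and SGK1 (1.28) higher and KLK3 and PLPP1 (-1.10) lower. Androgen-repressed genes were higher in 10 and lower in 6 of 27 without a camera call (adjusted p = 0.0601), and cofactor genes lower in 5 of 12 (GATA2 -0.78, HOXB13 -0.58; camera adjusted p = 0.104). Called by camera were also p53 targets (2 of 17 higher, TP53I3 1.00 and CDKN1A 0.51; adjusted p = 0.084 with an estimated correlation), basal genes (2 of 5 higher, LAMB3 2.03; adjusted p = 0.299 with an estimated correlation) and the leukocyte, endothelial and fibroblast markers (2 of 6 higher, VWF 0.40 and LUM 0.33; adjusted p = 0.252 with an estimated correlation). Of 15 housekeeping genes B2M was higher (0.72) and PGK1 (-0.59) and HPRT1 (-0.35) lower, without a camera call (adjusted p = 0.192). The share higher, 56.6%, was 74.2% with median scaling, which called 771 genes, and without F266S, G87R or L388M the count was 954, 513 and 827. In list counts with a construct left out, added after the data had been examined, lower hypoxia genes numbered 6 without F266S and 4 without G87R, higher ATF4 targets 7 without G87R or L388M. Lower G2/M genes numbered 4, 0 and 2 and lower S phase genes 2, 0 and 1 without F266S, G87R and L388M, and lower androgen-induced genes 7 without F266S and 6 without G87R. Without M253K the basal mean was 0.35 (0.63 with it) and that of the leukocyte, endothelial and fibroblast markers 0.13 (0.23 with it).

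Many genes called between knockdown and control cells were also called between forkhead and other mutants, in sets of arrays with none in common. Of 505 genes called in both, 475 had the same direction, 283 higher (37.95 for independent lists) and 192 lower (23.93 for independent lists). Comparisons of this fit share the residual variance of each gene, which may raise overlaps above those of independent lists whatever the direction. Genes with opposite directions numbered 8 and 22, against 29.11 and 31.19 for independent lists. FENG against wild type shared 580 called genes with the class contrast, all 580 in the same direction (379 higher and 201 lower, against 31.05 and 14.06 for independent lists), and 347 with the knockdown, 340 in the same direction. Across genes, which are not independent replicates, r was 0.55 between knockdown and class and 0.78 between FENG and class. How far each construct moved the knockdown genes back towards control cells was computed after the data had been examined. Over the 528 genes raised by the knockdown, the median change back, as a share of their median knockdown change, was 74.8% for wild type, 72.8% for G87R, 62.7% for L388M, 48.1% for D226N, 35.2% for F266S, 17.6% for FENG and -5.62% for M253K, where a simulated construct equal to knockdown cells gave 6.35% on average. Over the 434 lowered genes it was 68.4%, 69.1%, 58.4%, 37.6%, 23.4%, 16.0% and 11.2% in the same order, against 8.60%. The order of single constructs was not tested.

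**Figure D3:**
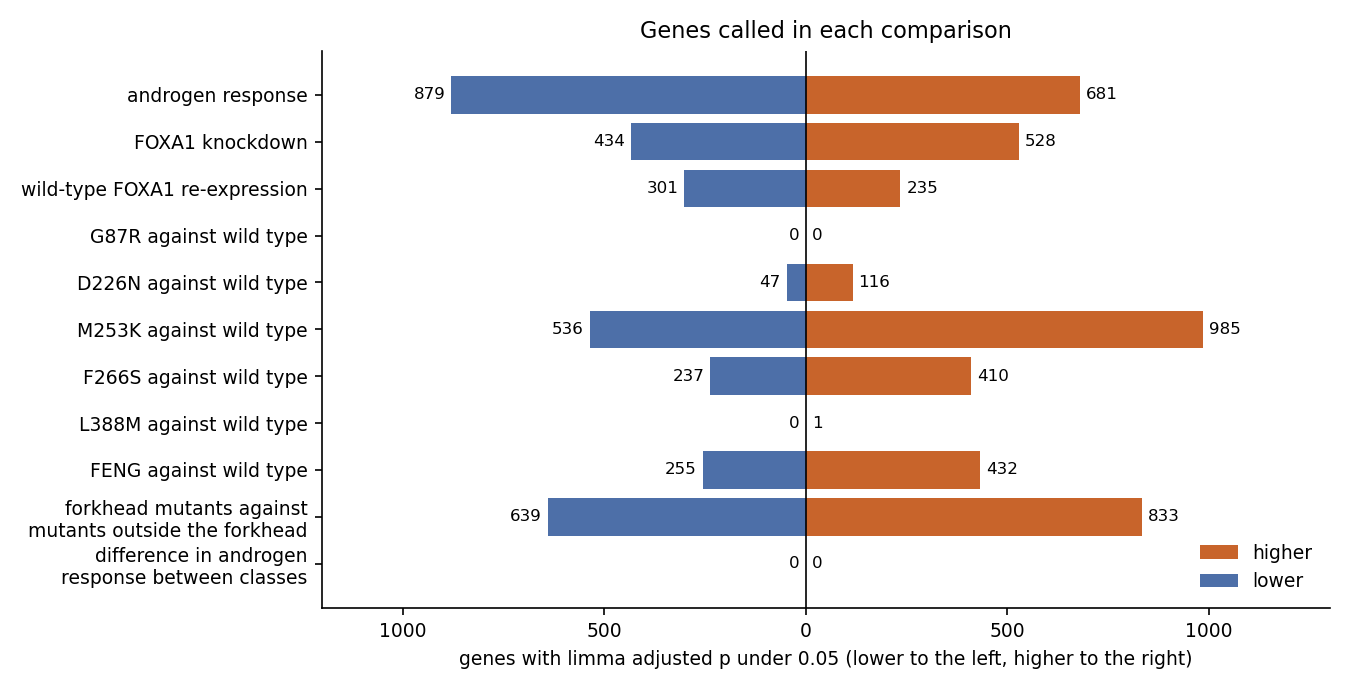
Number of genes with limma adjusted p under 0.05 (horizontal axis) in each of 11 comparisons (vertical axis), with bars to the right for higher and to the left for lower genes. M253K against wild type has 985 higher and 536 lower genes, whereas G87R has 0, L388M has 1, and the difference in response has 0.

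All constructs answered androgen, and the androgen-induced list rose by less on average in the forkhead mutants. Its mean log2 rise was 0.97 ± 0.10 (SD, n = 3) in D226N, M253K and F266S and 1.29 ± 0.03 (SD, n = 3) in wild type, G87R and L388M, a difference of -0.31 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). In ethanol the list stood at 7.48 ± 0.10 and 7.47 ± 0.03 (SD, n = 3 each), a difference of 0.0068 (exact permutation p = 0.9). Its ethanol level was lowest in control cells (7.21) and D226N (7.37), highest in FENG (7.66) and M253K (7.58), and 7.46 in knockdown and wild-type cells. Differences in response between single constructs thus come in part from the ethanol arrays. By construct the response was 1.52 in control, 0.91 in knockdown, 1.30 in wild type, 1.26 in G87R, 1.07 in D226N, 0.87 in M253K, 0.84 in FENG, 0.98 in F266S and 1.30 in L388M. The M253K, FENG and G87R values each include a deviating array. The difference was -0.26 without M253K and -0.33 without G87R. In R1881 arrays taken alone the median of the list against wild type was -0.34 for D226N, -0.37 for M253K, -0.37 for F266S and -0.27 for FENG, each at percentile 0 of 10000 random lists, and -0.02 for L388M (percentile 19.87) and -0.0011 for G87R (percentile 55.2). Knockdown cells with R1881 lay -0.42 below control cells (percentile 0), and wild-type FOXA1 0.47 above knockdown cells (percentile 100). Each of these percentiles sets 1 array against 1, and genes that move together on an array are not replicates, so they are no test between constructs.

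Gene by gene, the difference in response between these classes passed for 0 genes in limma (398 at an unadjusted p under 0.05). In 8.90% of genes the classes did not overlap, where chance gives 10%. The largest values that did not pass were KRTAP13-2 (2.17 ± 0.37, adjusted p = 0.699) and KRT16P2 (1.76) on the higher side and TARP (-1.60 ± 0.29, adjusted p = 0.699), TM4SF1 (-1.18) and SGK1 (-1.12) on the lower. FKBP5 rose by 2.68 in forkhead mutants and 3.21 in the others (-0.52 ± 0.18, adjusted p = 1.00), KLK3 by 1.59 and 1.62 (-0.04 ± 0.21) and TMPRSS2 by 1.24 and 1.46 (-0.23 ± 0.29). Camera at the preset correlation called a smaller response of the androgen-induced list (adjusted p = 5.02e-10), with 5 members lower when adjusted over the list alone, and a higher response of the androgen-repressed list (0.24, adjusted p = 4.88e-05). The latter was 0.85 over its 5 UGT2B genes, of uncertain family member, and 0.10 over the other 22, a split made after the data had been examined. For all 5 UGT2B genes M253K, with its deviating ethanol array, had the highest response of the forkhead mutants (UGT2B15 3.776, against -0.625 in D226N and -0.296 in F266S). With an estimated correlation the adjusted p was 0.271 for the androgen-induced and 0.142 for the androgen-repressed list. A count of 4 genes passed with median scaling, 9 with array weights and 1 without M253K.

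**Figure D4:**
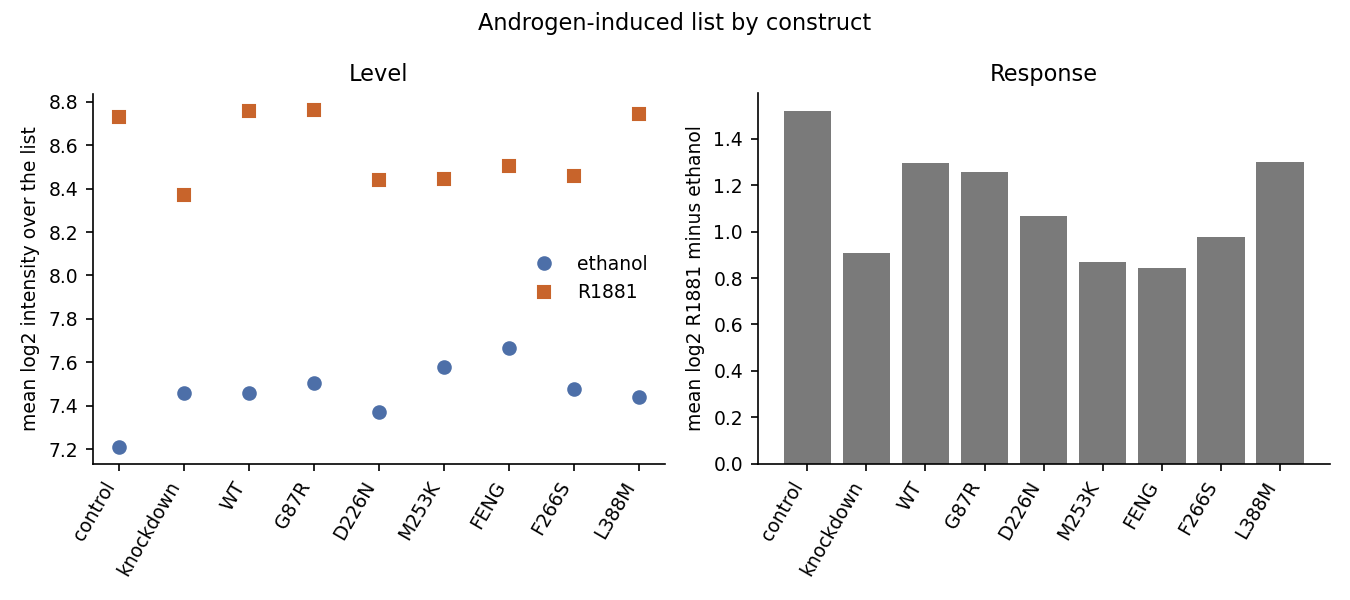
Mean log2 intensity over the 46 measured androgen-induced genes (left, circles for ethanol and squares for R1881) and their mean R1881 minus ethanol log2 difference (right, bars from 0) in each of 9 constructs (horizontal axis), 1 array per construct and treatment. The response is 1.52 in control cells and between 0.84 and 1.07 in knockdown, D226N, M253K, FENG and F266S cells.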

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

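The tests of overall signal, of probe pairs and of swapped arrays in this part, and leaving out UGT2B genes or constructs, were chosen only after the result was seen. A value was singled out when its distance to the nearest other construct was large against the range of all 9 constructs, which chance does in about 1 of 20 groups. This was done for 98 groups and singled out 6. FOXA1 in control cells stood apart in ethanol (11.92, nearest 11.15) and with R1881 (11.72, nearest 11.07), and all other constructs carried the hairpin. In M253K cells with ethanol the mean of the basal epithelial list was 6.213 (nearest 5.329) and that of the leukocyte, endothelial and fibroblast markers 5.673 (nearest 5.28). The response of the neuroendocrine list in M253K was -0.1548 (nearest 0.1037), and that of the S phase list in control cells was 0.3812 (nearest 0.1144).

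A difference in androgen response between the forkhead mutants and the set of wild type, G87R and L388M was called by camera for 5 lists. It was -0.3136 for androgen-induced genes (adjusted p = 5.02e-10), 0.2412 for androgen-repressed genes (adjusted p = 4.88e-05), -0.1927 for hypoxia (adjusted p = 0.00345), -0.2016 for polyamine metabolism (adjusted p = 0.00345) and -0.2191 for neuroendocrine genes (adjusted p = 0.0451). With an estimated correlation none passed (adjusted p = 0.271, 0.142, 0.617, 0.617 and 0.617). The androgen-repressed difference was 0.85 over 5 UGT2B genes and 0.10 over the other 22 members. M253K, whose ethanol array deviates, had the highest response of the forkhead mutants for all 5 UGT2B genes. For UGT2B15 it was 3.776, against -0.625 in D226N and -0.296 in F266S. The UGT2B difference without M253K was not computed. Without M253K the neuroendocrine difference was -0.11 and without L388M the hypoxia difference was -0.12. The other whole-list differences stayed within 1.5 times when a construct was left out. Over single genes 10 of the 10 splits of the 6 constructs gave as many genes as the real split (0, highest other 0), and 10 splits are too few for a share under 0.05.

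The first residual component of the additive fit held 52.8% of the residual variance. It stood at -0.53 for M253K ethanol, -0.39 for FENG R1881 and -0.19 for G87R ethanol. Their partner arrays stood at 0.53, 0.39 and 0.19, so the fit itself cannot tell which array of a pair deviates. A separate score for each array was -2.25, -0.99 and -0.68 on these 3 and 0.52 or above on the others. Probes of the same gene moved together less on the deviation than in the androgen response (r = 0.22 against 0.80 over 2983 probe pairs, difference -0.5718, 95% interval -0.62 to -0.53). A probe-level technical difference between arrays is therefore a candidate explanation. Low overall signal is argued against for G87R ethanol, which had 17058 detected probes (median 16788), whereas for M253K ethanol and FENG R1881 detected probes leave it open and it cannot be told apart (permutation p = 0.1843 for score and detected probes over 18 arrays), although L388M R1881, with 15922 detected probes and a score of 0.87, and mean raw signal go against it (267.4 for FENG R1881 with a median of 265.3, 256.4 for M253K ethanol, and 5 dimmer arrays with scores of 0.52 or above). A swap between treatments is argued against, since all 3 arrays had FKBP5 on the side of their own treatment (8.515 or below in ethanol, 10.68 or above with R1881). A first wording of that test asked for values within the range of the other arrays of the treatment and held for 2 of the 3, and no biological explanation was tested.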

How the results depend on the processing

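Leaving out 3 arrays that share a deviation and the residual covariate were chosen only after the result was seen. The androgen fit pairs the ethanol and R1881 arrays of each construct through its construct terms. Replicate numbers give no further pairing, since every condition has number 1 alone, and a slide block was not run because slides are not given in the sources used here. Among 515 pairs of a named gene and a comparison, 0 changed direction with a call in either fit under 7 alternatives. The same held for 368 pairs when only probes detected on all 18 arrays were used. A change of direction in a pair called in neither fit was not counted. Pairs that lost their call numbered 106 with median scaling, 43 without background correction, 31 without the filter, 29 with array weights, 24 with the mean over probes, 8 with an intensity trend and 4 with the deposited processed values. Of 69 list calls 9 passed with an estimated correlation (the androgen-induced list for R1881 and the inflammatory list in 8 comparisons) and 57 with fry. With median scaling the counts were 941 for androgen, 533 for knockdown, 326 for re-expression, 89 for D226N, 956 for M253K, 335 for F266S, 0 for L388M, 328 for FENG, 771 for the class contrast and 4 for the difference in response, and the median of all genes moved to -0.11, 0.17, -0.12, -0.10 and -0.21 for knockdown, re-expression, M253K, F266S and L388M. With array weights they were 2410 for androgen, 1227 for re-expression, 812 for D226N, 535 for M253K, 1888 for F266S, 7 for L388M and 9 for the difference in response. A fold of at least 1.5 left 394 for androgen and 578 for the class contrast, by its construction. Without construct terms 856 passed for androgen, and with the 4 arrays of the contrast alone 557 for knockdown and 899 for re-expression. Without the 3 arrays 1802 passed for knockdown, 1031 for re-expression, 347 for D226N and 1323 for F266S. The covariate gave 2826 for androgen, 1913 for knockdown, 1160 for re-expression, 8 for G87R, 404 for D226N, 3304 for M253K, 1465 for F266S, 3 for L388M, 1709 for FENG and 2871 for the class contrast, because it lowers the residual spread without moving an estimate. Leaving out arrays or constructs in turn gave 1182 to 1914 for androgen, 461 to 563 for knockdown, 207 to 276 for re-expression, 0 to 0 for G87R, 41 to 54 for D226N, 620 to 3204 for M253K, 205 to 277 for F266S, 0 to 0 for L388M, 197 to 709 for FENG, 513 to 1588 for the class contrast and 0 to 1 for the difference in response. The level of the androgen-induced list in ethanol changed sign without background correction (-0.01885), with probes detected on all arrays (-0.06033), with the mean over probes (-0.00375) and without M253K (-0.0439) or L388M (-0.00657), and leaving out each construct in turn gave -0.0439 to 0.05888. Its difference in response was -0.346 with FENG added to the forkhead mutants (exact permutation p = 0.0286, the smallest that this grouping can give), and -0.3622 to -0.2619 with constructs left out. FENG had been kept out of both classes, and its R1881 array is a deviating one. With median scaling its exact p was 0.3. Apart from the fold, the covariate and the arrays left out, the cause was not tested. Signal over background limits the dim genes, whose folds are given as bounds.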

Other observations

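Genes that androgen moved differently between single constructs were looked up only after the result was seen, and so was the test of whether the mutants only fail to reverse the knockdown. TRIM48 and TRIM51 rose with R1881 by 3.53 and 3.11 log2 units in control cells and by at most 1.16 and 0.75 in the other 8 constructs. A high level in ethanol went with this in wild-type, G87R, D226N and L388M cells (TRIM48 at 7.96 or above, against 4.92 in control cells). It did not in knockdown, M253K, FENG and F266S cells, where TRIM48 was at 4.89, 5.36, 5.50 and 6.63 in ethanol and higher with R1881 by 1.16, 0.32, 0.47 and 0.68. UGT2B15, a testosterone-conjugating enzyme, was higher with R1881 by 3.78 in M253K and lower in the other 8 constructs (-2.36 to -0.06). The M253K value comes from the deviating ethanol array (7.13, the lowest of the 9 ethanol arrays), since with R1881 M253K (10.9) lay near D226N (10.92) and F266S (10.9). The UGT2B15 responses of G87R (-0.06) and FENG (-2.29) also include a deviating array, at 8.71 in G87R ethanol and 8.68 in FENG R1881. AKR1C4 was higher with R1881 by 2.04 in M253K and lower in FENG (-1.74), again through the deviating arrays, with 7.31 in M253K ethanol and 7.66 in FENG R1881 against 9.35 and 9.40 on their partners. These are single arrays without a test, and which family member these probes read is uncertain.

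Genes responding to androgen in the other 8 constructs were used to gauge each construct. The median response of the induced genes came to 125% of that in the others for control, 96.6% for knockdown, 112% for wild type, 104% for G87R, 95.9% for D226N, 65.4% for M253K, 88.5% for FENG, 90.7% for F266S and 118% for L388M. For repressed genes it was 103%, 103%, 115%, 128%, 90.7%, 102%, 51.2%, 85.8% and 124% in the same order. The lowest of each, M253K for induced and FENG for repressed genes, include the M253K ethanol and FENG R1881 arrays that share the deviation.

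Exchanging treatment labels within constructs gave as many genes as the real labels in 1 of 100 splits, the real labels themselves (1560 genes, highest other 2). This argues against chance for the androgen response, as far as 100 splits can tell. For the class contrast 2 of the 10 splits of 5 constructs gave as many genes, the real split with 1472 and D226N, G87R and L388M against M253K and F266S with 1554. These splits are too few for a share under 0.05.

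Forkhead mutants might differ from wild type only by failing to reverse the knockdown. Of 975 genes called between D226N, M253K and F266S and wild type, 180 (18.46%) were also called against knockdown cells in the same direction, 158 higher and 22 lower, which argues against that explanation for these genes. They include UGT2B28 (2.80 above wild type and 5.48 above knockdown), UGT2B11 (2.66 and 5.27), the retinol dehydrogenase RDH10 (1.97 and 3.77), MMP10 (2.90 and 2.96), AGR3 (2.46 and 3.04), CCL20 (1.70 and 1.81), KLK3 (-1.52 and -1.19) and ACP3 (-1.62 and -0.91), chosen after their values were seen. Without the 3 deviating arrays 177 of the 180 genes were also found (287 of 1711 called genes, 16.8%), so these genes did not need those arrays to be called. Of the 3 only M253K ethanol enters either comparison, and called genes rose from 975 to 1711 without them. More calls favour keeping a gene, so this argues only weakly against the deviating arrays as the source. With the residual component as covariate 515 genes were found, but that component is orthogonal to the design, so this test was void. Whether the inserted FOXA1 copies were expressed at equal levels was not tested.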
